A study of Mus musculus with 6 samples.

How the data were processed

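Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in mouse colon epithelium. Crypt cells were sorted to 50000 per library, per the labels' protocols, and the libraries were sequenced as paired ends. The labels put 3 libraries in a group treated with DSS (dextran sulfate sodium, a chemical used to provoke colitis in mice) and 3 in an untreated group. The design text of the series also names germ-free conditions, but none of the 6 libraries carries such a label. The labels do not say whether the libraries of a group came from separate animals, and they give no sex or batch.

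The values analysed here come from 1 list of peaks. Per the peak names in the file, the authors called it with MACS2, under settings they named loose, on the reads of all libraries merged. The list therefore holds 1 value per region for both groups together, and 0 of its columns belong to a single library or group. Trimmomatic 0.39, Bowtie2, MACS2 and HTSeq and the genome build mm9 are named in the submitters' processing notes. The MACS2 version, its threshold, and the handling of duplicate reads, multiply mapped reads and blacklisted regions are not given in the sources used here. Each row gives the start and end of a peak, an integer score, a fold ratio, 2 significance values and the summit's offset from the start. The deposited fold ratio is the height of the merged read pileup at the summit over the caller's background. The deposited −log10 p-value and −log10 q-value compare the same pileup with that background, and the q-value is adjusted by the caller. The deposited score equalled 10 times the −log10 p, rounded down, in 100.0% of peaks. All 4 are the authors' values for each peak, and are used here only to describe, rank and filter peaks within the list.

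The background was worked out from the fold values, which step by a constant. With a pseudocount of 1 on the pileup and the background, as MACS2 uses, the values of all 961 distinct folds were whole pileups (within 0.05) over a single background of 31.995. The Poisson probability of each pileup under that background differed from the deposited −log10 p by at most 0.000219 over the 387626 peaks with a −log10 p below 200. The background was thus the same for every peak, with no local term. The lowest pileup was 39, with a fold of 1.21 and a deposited −log10 p of 1.02. A pileup of 38 would have a −log10 value of 0.898, so the list ends where the Poisson probability passes 0.1. The narrowest peak was 73 bp wide and the shortest gap between peaks was 74 bp. Pileups here are numbers of overlapping reads or extended fragments in the merged libraries, and which of these was not stated. The depth of the single libraries is unknown, so no interval that needs it is given. Intervals on shares of peaks are 95% Wilson intervals, and those on densities are exact 95% Poisson intervals. They cover counting error only, and neighbouring peaks are not independent.

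Peaks with a caller q under 0.01 are called strong here, and those with a q of 0.05 or more weak. Density is the number of peaks per Mb between the first and the last listed peak of a chromosome, since chromosome lengths of the build were not used here. Strong peaks were joined into clusters where the gap was at most 12.5 kb. Coordinates are those of the list, in mm9, counted from 1. The gene table at hand follows another assembly (GRCm38.p6), so 0 peaks were assigned to genes, and promoter, gene-list and motif comparisons were left out. Group differences in accessibility, in reads per library and in signal composition, planned before the data were examined, could not be computed from a merged list. The planned rule for naming changed peaks could not be applied either. The regions named here are the tallest and widest peaks, the clusters with the most peaks, the densest windows of 1 Mb and the longest stretches without a peak. These rules, and all other settings, were chosen after the data were seen.

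Densities were correlated over the 19 autosomes with permutation tests of 100000 resamples. Pileup scales were fitted by the smallest Kolmogorov-Smirnov distance, with 1000 bootstrap draws of 10 Mb blocks. Tested on simulated data of 768 peaks, as many as chromosome X had at a pileup of 60 or more, the fit gave a mean of 0.497 (SD 0.050, 100 draws) for a true factor of 0.5, and 1.00 (SD 0.018) for a true factor of 1.0. For a true factor of 0.75 it gave 0.756 (SD 0.053). The simulated peaks were independent draws of autosomal pileups times the factor, so these SDs do not give the accuracy on X itself. Alternatives were the q threshold, the peak width, merging of neighbours, the joining distance, leaving out chromosome ends, autosomes or the tallest pileups, the pileup minimum, the fold limit and the minimum size of clusters, the distance from a chromosome end and the number of tallest peaks. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.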

Results

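Open chromatin was profiled by ATAC-seq in colon epithelium from DSS-treated mice (3 libraries) and untreated mice (3 libraries). The comparison that the design implies is between these groups, and the series places it in a study of inflammation and the microbiota. The values analysed here describe merged libraries, taken to be these 6, although the peak names say only that all were merged. They show where reads from both groups together were listed above the background, and by how much, but not whether a region gained or lost accessibility under DSS. No difference between the groups, no replicate error and no depth per library can be given. There are no replicates behind any value of a single peak.

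The merged libraries held 391833 listed regions on the 19 autosomes, X and Y, covering 134 Mb. Most were short and barely above the background. The median width was 186 bp (quartiles 122 and 347 bp) and the median fold at the summit was 1.39 (quartiles 1.30 and 1.52). In 294021 of the regions (75.04%) the summit pileup was between 39 and 49, against a background of 31.995. Regions with a caller q under 0.05 numbered 86721, or 22.1% of the list (95% interval 22.0% to 22.3%). Strong peaks, with a q under 0.01, numbered 59730, or 15.2% (15.1% to 15.4%). Their median width was 833 bp, their median fold was 2.21, and they covered 64.8 Mb. At a q under 1e-05, 35682 peaks were left, with a median width of 1125 bp and a median fold of 3.24. The remaining 305112 regions, with a q of 0.05 or more, had a median width of 153 bp.

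Taller peaks were wider over most of the range. A relation of this kind is partly built in, since all regions were called against the same background and cutoff. The median width was 150 bp at pileups of 39 to 49, 700 bp at 60 to 79, 1528 bp at 160 to 319 and 2337 bp in the 666 peaks at 640 to 1199. The 61 tallest peaks, with a pileup of 1200 or more, departed from this order. Their median width was 1137 bp, with quartiles of 515 and 5861 bp, against quartiles of 1873 and 3127 bp in the class before. The median was lower by 1200 bp than in the class before (two-sided permutation test over peaks, p = 1e-05, the smallest that 100000 resamples can give). The upper quartile was higher. Peaks are not independent replicates, and the test describes this list.

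**Figure D1:**
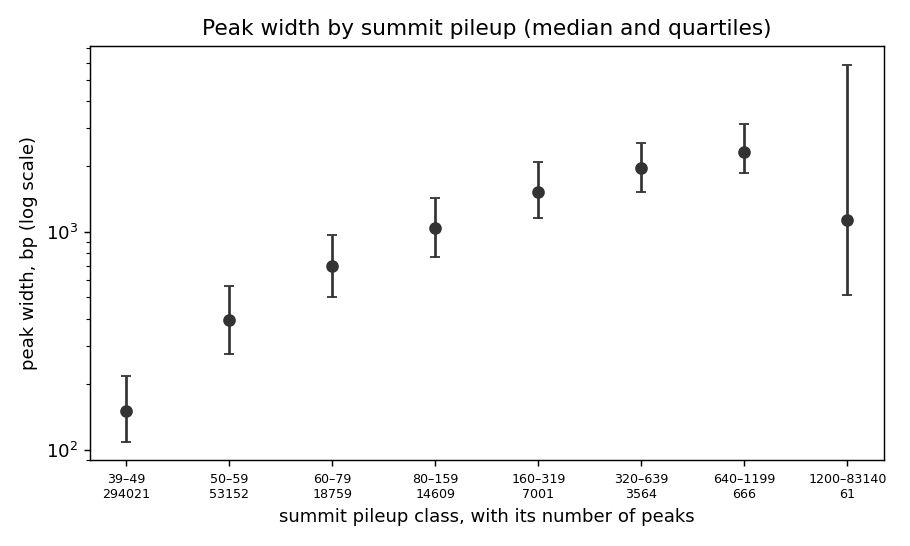
Peak width in bp (log scale) by class of summit pileup, in the merged libraries. Points are medians, bars run from the lower to the upper quartile, and the number of peaks in each class stands under its range. The median rises from 150 bp to 2337 bp over the classes below a pileup of 1200 and is 1137 bp in the class above.

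Listed regions were spread unevenly over the chromosomes. The 19 autosomes carried 160 ± 27.8 listed regions per Mb (mean ± SD over chromosomes, n = 19). Chromosome 11 was the densest, with 214 per Mb, and chromosome 3 the sparsest, with 119 per Mb, a ratio of 1.79. For strong peaks the autosomal mean was 24.5 ± 4.67 per Mb. Chromosome 11 again had the highest value, 33.8 per Mb (95% interval 32.7 to 34.8). Chromosomes 17 and 19 followed at 30.7 and 29.9 per Mb, and chromosome 18 had the lowest autosomal value, 17.3 per Mb (16.4 to 18.2). Autosomes with many strong peaks per Mb also had many weak ones. Over the 19 autosomes, Pearson's r was 0.87 (permutation p = 1e-05, the smallest possible) and Spearman's rho was 0.84 (permutation p = 3e-05). Without chromosomes 11 and 18, which lay farthest from the median, r was 0.81 (permutation p = 0.0001). These p-values all concern the same relation and were not adjusted. Both densities were divided by the same span, and the settings were chosen after the data were seen.

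Chromosome X stood apart from every autosome. It held 2210 listed regions, or 13.5 per Mb (12.9 to 14.1), which is 0.084 of the autosomal mean. The lowest autosome reached 0.743 of that mean. The gap was smaller for strong peaks, of which X held 931, or 5.69 per Mb (5.33 to 6.07), 0.233 of the autosomal mean. Strong peaks made up 42.1% of the regions on X (40.1% to 44.2%), against 13.9% to 18.96% on the single autosomes. Their median fold on X was 2.49, against 2.23 ± 0.068 on the autosomes. Chromosome Y held 123 regions between positions 94660 and 2652334, of which 44 were strong. The tallest of them, at 2652209 to 2652334, reached 12.1-fold. The labels give no sex for any library.

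**Figure D2:**
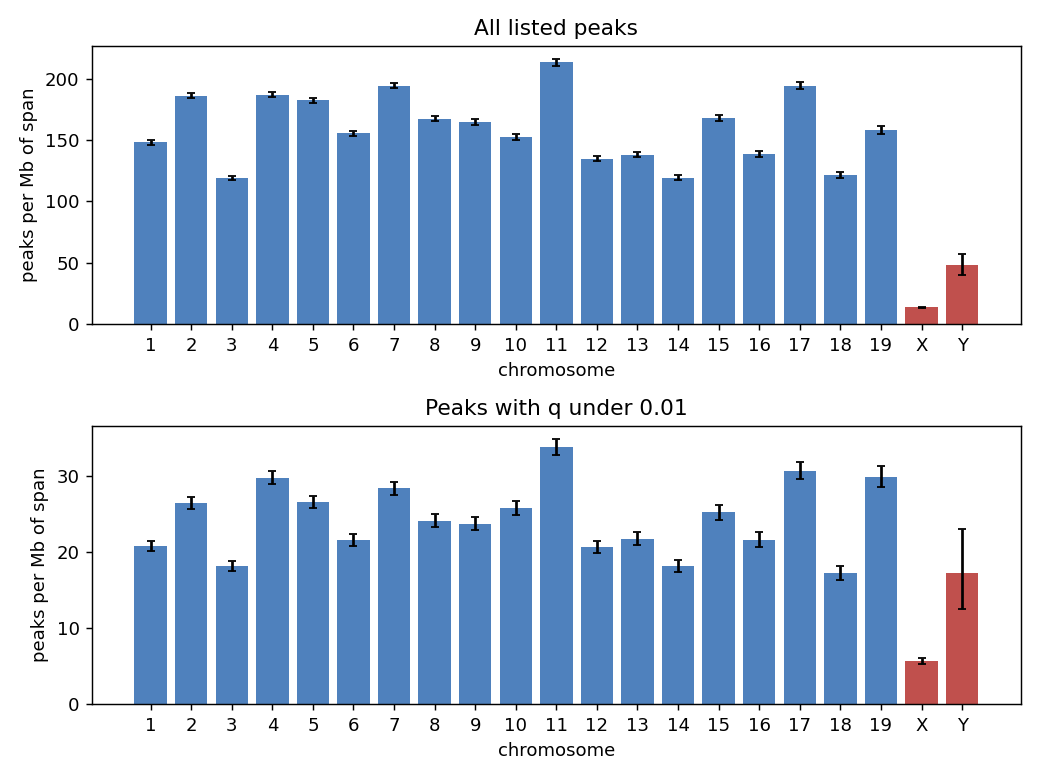
Peaks per Mb of span on each chromosome, for all listed peaks (top) and for peaks with a q under 0.01 (bottom), in the merged libraries. Bars are densities with exact 95% Poisson intervals, blue for autosomes and red for X and Y. X stands at 13.5 per Mb for all peaks and 5.69 for strong peaks, below every autosome in both.

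The contrast between X and the autosomes changed with the height of the peaks. At a pileup of at least 39, 60, 100, 200 and 400, the density on X was 0.084, 0.258, 0.259, 0.195 and 0.075 of that on the pooled autosomes. When X at a given pileup was set against the autosomes at the doubled pileup, the ratio was 1.24 at 39, 0.913 at 50 and 0.737 at 60. It lay between 0.530 and 0.703 at minimums from 80 to 400, where X held 477 down to 14 peaks. At 600, where X held 6 peaks, it was 1.58.

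**Figure D3:**
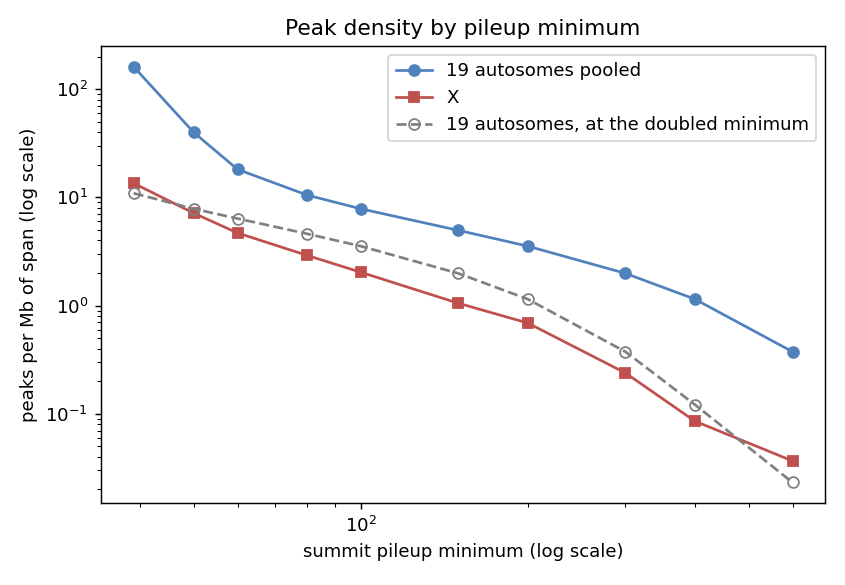
Peaks per Mb (log scale) with a summit pileup of at least the value on the horizontal axis (log scale), in the merged libraries. Filled circles are the 19 autosomes pooled, squares are X, and open circles are the autosomes counted at the doubled minimum. X lies below the autosomes at each minimum, at 0.084 of their density at 39 and 0.277 at 80.

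Part of the strong peaks lay in clusters. Joined over gaps of at most 12.5 kb, the 59730 strong peaks formed 24196 clusters, of which 13684 (56.6%) were single peaks. A further 820 clusters held 10 or more peaks each and together took 13585 strong peaks (22.7%). The number of such clusters was 1643 at a q under 0.05 and 224 under 1e-05, and 255 and 1386 with joins of at most 5 and 25 kb. No chance value for the clustering was computed. Windows of 1 Mb held a median of 14 strong peaks (quartiles 4 and 35), and 135 of 2593 windows held none. The 2 densest windows lay side by side on chromosome 4, from 145 to 147 Mb, with 284 and 281 strong peaks. The next 2 lay on chromosome 10, from 79 to 81 Mb, with 189 and 213. Windows at 73 to 74 Mb on chromosome 8 and 167 to 168 Mb on chromosome 2 followed, with 140 and 137 strong peaks. The window at 95 to 96 Mb on chromosome 5 held 133, of at most 2.64-fold, and the window at 35 to 36 Mb on chromosome 17 held 132.

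The clusters with many strong peaks differed in height and in covered percent. The cluster with the most peaks, on chromosome 4 at 146468661 to 147195958, held 231 strong peaks that covered 67.4% of its 727298 bp. Its median fold was 2.45 and its tallest peak reached 11.5-fold. Its size depended on the settings. The largest cluster held 72 peaks with joins of at most 5 kb, and at a q under 1e-05 another chromosome 4 cluster, at 145251113 to 145489635, was the largest with 67. At a q under 0.05 the largest held 265 and with joins of at most 25 kb 242, and both contained the main one. The cluster at 84951739 to 85343555 on chromosome 1 held 148 peaks and covered 61.9% of its span, with a maximum of 8.79-fold. The cluster at 145130397 to 145489635 on chromosome 4 held 139 peaks and covered 53.1%, with a maximum of 7.06-fold. On chromosome 5, at 94778680 to 95065511, 96 strong peaks covered 33.3% of the span and reached at most 2.39-fold. On chromosome 13, at 12832892 to 13089577, 61 peaks covered 69.9% of the span with a maximum of 3.39-fold. The chromosome 10 clusters held taller peaks, while their covered percents overlapped those of the clusters above. The one at 80680218 to 80898100 held 67 peaks, covered 42.5% and reached 25.5-fold. The one at 79224325 to 79460688 held 59 peaks, covered 34.1% and reached 20.8-fold, and the one at 79475052 to 79645660 held 54 peaks, covered 54.1% and reached 25.5-fold. On chromosome 8, the cluster at 73026417 to 73255296 held 45 peaks, covered 35.3% and reached 24.2-fold. Other clusters were both tall and densely covered. The one at 87343856 to 87564913 on chromosome 1 held 87 peaks, covered 63.1% and reached 15.6-fold. The one at 19680663 to 19802790 on chromosome 8 held 31 peaks, reached 43.3-fold and covered 83.3%, the highest percent among the 51 clusters of 30 or more peaks.

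**Figure D4:**
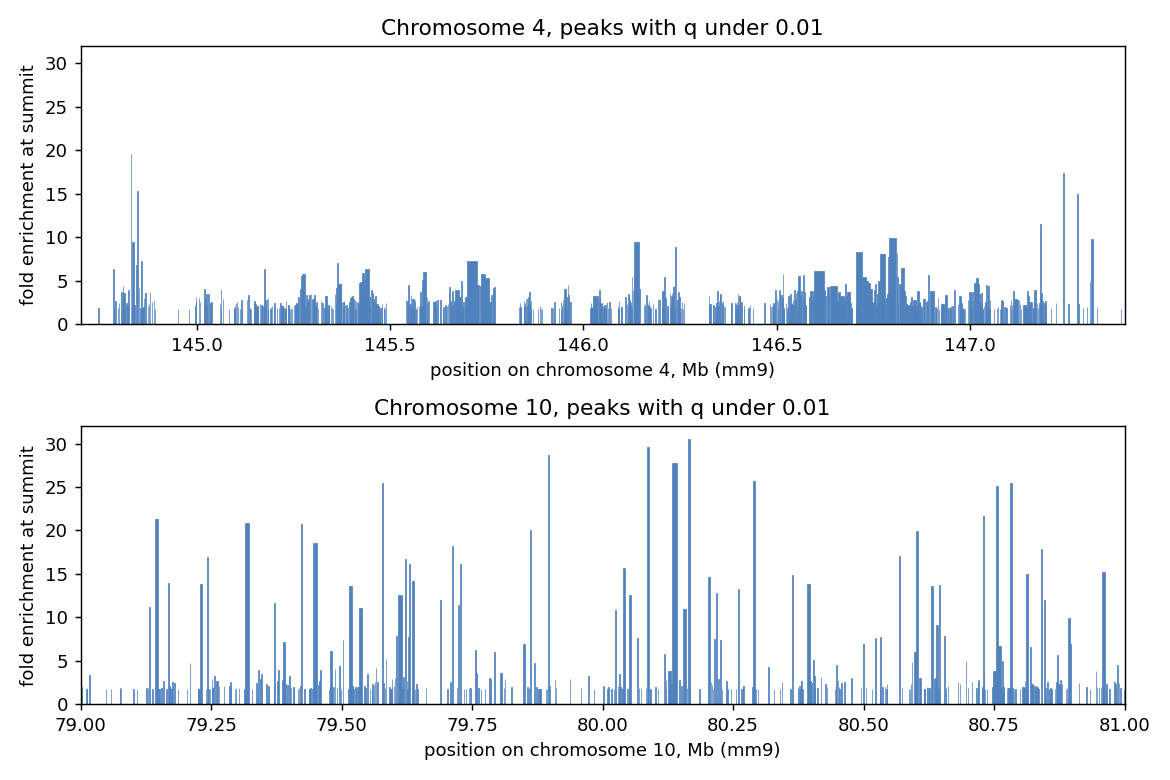
Strong peaks (q under 0.01) along the densest region of chromosome 4 (top) and of chromosome 10 (bottom), drawn to scale by position in Mb (mm9), with fold enrichment at the summit as height. The cluster with the most peaks reaches 11.5-fold on chromosome 4 and 25.5-fold on chromosome 10.

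The tallest peaks held more of the summed summit pileups than their share of the list, which ranking by height fixes in advance. Each region counts once by its summit, whatever its width, so these are not shares of reads. The 10 tallest made up 0.982% of all summit pileups added together, and the 10000 tallest, or 2.55% of the list, made up 16.8%. The tallest peak, on chromosome 2 at 98506375 to 98507511, was 2520-fold over the background, with a pileup of 83140. A pair of further peaks among the 8 tallest lay within 5 kb of it, at 98502380 to 98503155 (423-fold) and 98505041 to 98505395 (262-fold). The next in height was on chromosome 9 at 2999984 to 3038342, the first listed region of that chromosome, at 1225-fold. It was followed by chromosome 1 at 24618374 to 24623023 (757-fold) and chromosome 9 at 35112791 to 35113194 (493-fold). Chromosome 17 at 13732871 to 13746080 (273-fold) and chromosome 4 at 118219622 to 118221711 (261-fold) completed the 8 tallest. For comparison, 294021 of the listed regions had a pileup of at most 49.

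Some listed regions were far wider than a single open site. The widest spanned 80413 bp on chromosome 11 at 3019662 to 3100074, with a maximum of 86.0-fold. Others spanned 59228 bp on chromosome 1 at 90107705 to 90166932 and 49999 bp on chromosome 8 at 19952615 to 20002613. On X, a region of 39297 bp lay at 166407742 to 166447038 and reached 60.6-fold. At the other extreme were long stretches with no listed region. The median gap between neighbouring regions was 1601 bp (quartiles 473 and 5218 bp). The longest gap was 7001481 bp on chromosome 7, from 39356058 to 46357538. It was followed by 2047135 bp on chromosome 8, from 20038561 to 22085695, and 2000300 bp on chromosome 1, from 85343556 to 87343855. Of the 15 gaps over 900 kb, 10 were on X. Long gaps there go with its low density, 13.5 listed regions per Mb against a mean of 160 on the autosomes. The number to be expected from that density was not computed. The chromosome 1 gap was bounded on both sides by clusters of strong peaks, with 148 peaks before it and 87 after it (87343856 to 87564913).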

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

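The alternatives planned before the data were examined all concerned the DSS comparison and were not run, since the merged list gives no value per library. All alternatives here were chosen after the data were seen, and every result is a description of 1 merged list without replicates. No paired analysis was possible because no column carries a library. The number of peaks depended most on the threshold: 86721 at a q under 0.05, 59730 under 0.01 and 35682 under 1e-05. It was 238724 at widths of 150 to 2000 bp and 236738 with neighbours within 1000 bp merged. X density relative to autosomes moved from 0.084 to 0.190, 0.233 and 0.268 at those q thresholds, to 0.102 under the width limit and to 0.104 after merging. The ratio of the highest to the lowest autosome moved from 1.79 to 1.99 at a q under 0.05 and to 1.51 after merging. Clusters of 10 or more peaks numbered 820 in the main setting, 1643 at a q under 0.05, 224 under 1e-05, 255 with joins of at most 5 kb and 1386 with joins of up to 25 kb. The largest cluster, 231 peaks in the main setting, held 72 with joins of at most 5 kb, within the main one, and 67 at a q under 1e-05, where another chromosome 4 cluster took first place. It changed less at a q under 0.05 (265 peaks) and with joins of up to 25 kb (242 peaks). The higher covered percent of low clusters (8.44 points) lost its p under 0.05 in each alternative: 8.72 points with a fold limit of 8, 4.99 with 16, and 1.75 over clusters of 20 or more peaks. Loci of the tallest peaks near chromosome ends were 10 of 41, against 9 of 41 within 200 kb, 11 of 41 within 1000 kb, 12 of 84 for the 100 tallest and 9 of 42 for peaks of at most 5000 bp. The causes were not tested. The factor between X and autosomal pileups was 1.03 in the main setting, but 0.90, 0.38 and 0.46 at pileup minimums of 50, 80 and 100 and 0.31 without pileups of 1200 or more, on both sides of 1 and within its interval of 0.30 to 1.08.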

Other observations

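Of the tests in this part, those of weak peaks around strong ones and of peak heights within clusters were set out before their values were seen, and the others after. Weak regions were not scattered evenly around the strong ones. On the autosomes, 16.2% of the 303938 weak regions had their summit within 2 kb of the summit of a strong peak, against 8.61% ± 0.260 (SD) when they were shifted along their chromosome by a random distance. The highest of the 100 shifts gave 9.42%, so placement without regard to strong peaks is argued against for the excess. The list allows gaps as short as 74 bp. Flanks of strong peaks listed as separate regions were not told apart from regional density that weak and strong regions share. The shares also mean that most weak regions lay farther than 2 kb from a strong peak.

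The shortage of peaks on X may reflect lower coverage of the whole chromosome against a single genome-wide background. A shortage of open sites that left coverage ordinary would keep regions near the background, but strong peaks made up 42.1% of the regions on X against at most 18.96% on an autosome. Silencing of a copy of X, with both copies still adding to the background, would also keep such regions. Those with a pileup under 50 were 0.053 as dense as on autosomes, where the sparsest autosome reached 0.751. But regions under 50 are 75.04% of the list, so both comparisons largely restate the shortage itself. They were set after it was seen, and are not independent tests against either explanation. Whether coverage was halved, as with 1 copy of X per cell, cannot be told apart from other losses: the best factor between X and autosomal pileups was 1.03 at a pileup minimum of 60, with an interval of 0.30 to 1.08 that reached the lower limit of the search. It was 0.90 at a minimum of 50, 0.38 at 80, 0.46 at 100 and 0.31 without pileups of 1200 or more, while the autosomes gave 0.94 to 1.06 at 60. The factor of 1.03, the test first set for a shortage of sites, lies within that autosomal range and so goes with ordinary coverage, but X matched poorly at any factor (distance 0.068, against at most 0.026 on an autosome), and the share of strong peaks was taken as the test only afterwards. Halved coverage alone would put X level with the autosomes counted at the doubled pileup. The ratio of X to them was 0.53 to 0.70 at pileup minimums from 80 to 400, where X held 477 down to 14 peaks. No interval or spread over single autosomes was computed for this ratio. For strong peaks the sparsest autosome itself reached only 0.706 of the autosomal mean. Whether X is short of tall peaks beyond halved coverage was thus not tested. It was 0.737 at 60 and 0.913 at 50, but 1.24 at 39 and 1.58 at 600, where X held 6 peaks. Lower coverage together with fewer open sites was not tested and stays open. On Y, strong peaks had a density of 17.2 per Mb (12.5 to 23.1), near that of the lowest autosome (17.3). Over all listed regions Y had 48.1 per Mb, against 119 on the lowest autosome, and 35.8% of them were strong, so on these measures it departed from the autosomes in the same direction as X. The median fold of strong peaks went the other way. It was 1.97 on Y, below the lowest autosome (2.12), and 2.49 on X, above the highest (2.42). Whether the peaks on Y came from male cells or from similar sequence elsewhere was not tested, and the sex of the animals and read loss in mapping stay open.

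The long clusters of low peaks, such as those at 145 to 147 Mb of chromosome 4, may be regions where many near-identical copies raise coverage as a whole. Among the 51 clusters of 30 or more peaks, the 24 without a peak of 12-fold covered 46.7% ± 16.2 of their span. The other 27 covered 38.2% ± 12.7, a difference of 8.44 points (permutation p = 0.0444). It lost its p under 0.05 in every alternative tried, none of which changed the joining distance. With joins of at most 25 kb, the largest chromosome 4 cluster also took in peaks of 17.3-fold and 14.9-fold. It would then not count as low. Of the low clusters 95.8% had a ratio of maximum to median fold below all tall clusters, but splitting clusters by their maximum fixes that outcome, so ordinary open sites lying close together stay open. Of the 5 longest autosomal stretches without a peak, 3 ended within 100 kb of such a large cluster, against 2 of 1340 other stretches of 100 kb or more. This count was made after the chromosome 1 gap between 2 large clusters had been seen, which is among the 3, so it is no independent evidence. Whether those stretches hold assembled sequence, and the clusters repeated sequence, cannot be told apart from other explanations without the mm9 sequence, which was not used here.

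The tallest peaks are a candidate for signal of another origin than ordinary open sites. Their median width was lower than in the class before by 1200 bp (a change of -1200 bp), against the rise over all lower classes. Their widths were also more spread, with quartiles of 515 and 5861 bp against 1873 and 3127 bp, so the upper quartile was higher. The class limit and the width test were set after the data were seen. Grouped by Mb, the 50 tallest made 41 loci, of which 10 lay within 500 kb of the first or last listed region of a chromosome, or 24.4% (13.8% to 39.3%), against 1.51% of the 2458 loci with a strong peak (exact binomial test, p = 4.37e-10). The test was set after the data were seen. Some of the tallest peaks are themselves the first or last listed region of their chromosome. The p-value is thus no independent evidence against placement by chance, and 31 of the loci lay elsewhere. The share depended on how many peaks were taken: with the 100 tallest it was 12 of 84 loci, or 14.3% (8.37% to 23.3%; exact binomial test, p = 5.602e-09). Multi-copy sequence at the ends of the assembled chromosomes may account for part of them, but with no repeat annotation of mm9 used here this stays open.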
